A study of Caenorhabditis elegans with 6 samples.

How the data were processed

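Whole-worm RNA from 6 dishes was hybridised to Affymetrix C. elegans arrays, 1 per dish, with 3 arrays labelled control and 3 labelled Au-NP. Per the labels' protocols, RNA was extracted with Trizol, purified on a column, and 2 µg of it was turned into biotin-labelled cRNA. The labels speak of replicates in separate dishes of one experiment and do not say that the worms came from separate cultures, so the p-values measure the spread between dishes.

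The deposited values are on the log2 scale, 1 per probe set and array, and were made with RMA per the submitters' processing notes, which also name Partek 6.4 without giving its role. RMA corrects the background, quantile-normalizes the arrays together and summarises the probes of a set. It compresses small signals toward the background and assumes that most transcripts do not differ between arrays. The table itself names no scale. Its values lay between 3.44 and 15.2 with array medians near 7, which is what RMA gives as log2, and no further transformation or centring was applied. Scanner files and detection calls were not used here, so it was not decided which probe sets lay above background. The genome build and annotation behind the array are not given in the sources used here, and no coordinates are printed for that reason.

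Probe sets were named from the platform annotation. It gave 20766 of the 22548 tested probe sets a single gene symbol, 887 several symbols and 895 none, and probe sets with several symbols were tested but not named. Of those with a single symbol, 20701 were found by gene identifier in the reference gene table of assembly WBcel235, which changed 0 symbols, and the named probe sets covered 17118 genes. Gene span was the length in that table from the start to the end of the gene with introns.

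Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited values, a model with the group alone, Au-NP minus control, two-sided), with Benjamini-Hochberg adjustment over the 22548 probe sets and a threshold of 0.05. The fit had 4 residual degrees of freedom and a prior of 3.39. Errors of log2 differences are the moderated standard errors of that fit, with n = 3 arrays per group. A gene counted as higher or lower when at least 1 of its own probe sets passed in that direction. Replicate pairs were compared before averaging, and between 4 and 15 of the 22548 values were identical in any 2 arrays, so every array counted as its own sample.

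Before the data were examined, 32 gene lists, the design and a rule for naming genes were fixed. The rule took the 12 genes with the largest log2 change in each direction among probe sets past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and the stress, uptake, metal, cuticle and yolk genes hsp-4, hsp-16.2, abu-11, pqn-5, apl-1, rme-2, chc-1, dyn-1, mtl-1, mtl-2, pcs-1, gst-4, sod-3, cyp-35A2, col-19 and vit-2. Of those, pqn-5 had no probe set of its own. Genes named outside the rule are said to be so where they appear. Lists were tested on 1 probe set per gene, the one with the highest mean over the 6 arrays, with limma's camera at an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. The lists covered the abu and pqn genes, endoplasmic reticulum, heat-shock and mitochondrial stress genes, antioxidant, metal-response, cytochrome P450 and glucuronosyltransferase genes, endocytosis, lysosome, amyloid processing, calcium signalling, immunity, C-type lectins, starvation, lipid metabolism, yolk proteins, collagens, moulting, ribosome, proteasome, respiratory chain, cell cycle, cell death, and markers of intestine, muscle, pharynx, hypodermis, neurons, germ line, sperm and oocytes.

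Alternatives set in advance were the replicate number as a block, leaving out each array, quantile normalization again, centring on array medians, filters on low probe sets, array weights, leaving out probe sets whose suffix marks possible cross-hybridization, trend and robust or gene-wise variances, other thresholds, 1 probe set per gene, camera with an estimated correlation, fry, the mean of a gene's probe sets, and lists without shared genes. A correction of each array for its lowess trend with log2 gene span was added after the calls were seen to differ in span. The limma fit and camera at the preset correlation were tested on simulated data with the 22548 probe sets and arrays of the Au-NP against control comparison. There were 5 runs with 200 changed probe sets. Of changes of 0.5, 1 and 2 log2 units, 21.8%, 88.2% and 98.5% were recovered, with 6.8 false calls per run on average. A list that was shifted was called in 5 of 5 runs with 0 other lists called. The simulated noise was independent between probe sets, and no array was set apart. Estimated correlations within the real lists reached 0.79 (sperm), so these runs do not show how often camera calls lists whose genes vary together. The other settings were not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.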

Results

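Messenger RNA levels were measured in whole Caenorhabditis elegans worms of the wild-type strain N2 with Affymetrix arrays, 1 array per RNA sample. Larvae of the third stage (L3), matched in age and reared at 20 °C, were placed in dishes of dilute salt solution (50% K-medium) with about 2000 worms to a dish and 3 dishes per treatment. The Au-NP group was given gold particles 4 nm in diameter with a citrate coat at 5.9 mg/L for 12 h, a concentration that the labels call the LC10. The dishes then held particle-free medium for a further 12 h, and RNA was taken at 24 h. The labels name the other group only as control. The design thus has 2 groups of 3 arrays, and the question it addresses is which transcripts differ between exposed and unexposed worms after this recovery period.

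The table held 22625 probe sets, of which 77 Affymetrix control probe sets were left out and 22548 were tested. The array medians were 7.06, 7.05 and 7.09 on the log2 scale for control replicates 1 to 3, and 7.06, 7.03 and 7.06 for Au-NP replicates 1 to 3. The number of arrays limits the precision of every value given here. Correlations between arrays (Pearson's r across probe sets, which are not independent replicates) were 0.996 for each pair of controls and 0.997 for Au-NP replicates 1 and 2. Au-NP replicate 3 stood apart from its own group, with r of 0.988 to replicate 1 and 0.990 to replicate 2, where arrays of different groups had 0.985 to 0.990. The first principal component held 54.3% of the variance, and on it the controls lay at -25.4, -14.8 and -25.2, Au-NP replicates 1 and 2 at 28.2 and 31.4, and Au-NP replicate 3 at 5.83. On the second component, with 27.2% of the variance, Au-NP replicate 3 lay at 34.2 and every other array at or below 2.24.

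Transcripts of several abu and pqn genes, which encode proteins rich in glutamine and asparagine, showed the largest differences between the groups. They were lower in the arrays labelled Au-NP. The abu-15 signal was 11.6 ± 0.30 (SD, n = 3, log2) in the control arrays and 8.46 ± 0.96 in the Au-NP arrays, a log2 difference of -3.15 ± 0.43 (SE) and a fold of 8.87. Muscle myosins, germ-line RNA-binding proteins, eggshell proteins and endocytic coat proteins also had members that were lower. Secreted peptides and glutathione S-transferases had members that were higher by smaller amounts. The direction of every value here is that of the array labels. It is opposite, for the abu and pqn genes and for several chaperones, to the direction of the published account of this experiment as it is remembered here. That recollection was not checked and can itself be mistaken, and nothing in the values or labels used here settles which is right, so "lower" and "higher" below mean lower and higher in the arrays labelled Au-NP.

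Of the 22548 probe sets, 2689 (11.9%) passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, 1408 of them higher and 1281 lower in the Au-NP arrays. They named 1282 genes that were higher and 846 that were lower, and 0 genes had probe sets past the threshold in both directions. The falls were larger than the rises, since 232 probe sets were lower by at least 1 log2 unit and 7 were higher by that much. The median change was 0.46 log2 (1.37-fold) among the higher probe sets and -0.64 log2 (1.56-fold) among the lower ones, and the median over all tested probe sets was 0.03. In all 2689 the 3 Au-NP values lay wholly above or wholly below the 3 control values, as they did for 30.8% of all tested probe sets, where chance gives 10%. The counts depended on single arrays, and without control replicates 1, 2 and 3 in turn they were 402, 337 and 309 higher and 557, 640 and 533 lower. Without Au-NP replicates 1, 2 and 3 in turn they were 666, 146 and 2047 higher and 1118, 410 and 1953 lower, so that leaving out Au-NP replicate 3 raised both counts.

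Among the 12 genes with the largest falls, 6 belonged to the abu and pqn list. Besides abu-15 (limma adjusted p = 0.00792) these were abu-6 at -3.09 ± 0.40 (SE), abu-8 at -2.84, pqn-75 at -2.29 ± 0.22, pqn-74 at -2.08 and pqn-54 at -2.02 ± 0.13. The remaining 6 were ZK180.5 at -2.61, cut-2, a cuticlin of the worm's outer coat, at -2.47 ± 0.55, Y47D7A.13 at -2.23, gsa-1, which encodes the alpha subunit of the stimulatory G protein, at -2.1 ± 0.14, spat-2 at -1.89, and gpb-1, a G protein beta subunit, at -1.87. The limma adjusted p of these 12 genes ranged from 0.00170 for gsa-1, pqn-54 and spat-2 to 0.0305 for cut-2. For gpb-1 3 of 3 probe sets passed the threshold, and for gsa-1 1 of 2 did. The probe sets of abu-15, abu-6, abu-8, pqn-74, ZK180.5 and cut-2 carry suffixes that mark possible cross-hybridization between related genes.

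The 12 genes with the largest rises changed by less. They were F14H3.12 at 1.35 ± 0.18 (SE, log2), F45D11.1 at 1.25, F14F9.6 at 1.22, the insulin-like peptide gene ins-22 at 1.20 ± 0.23, spig-20 at 1.05, ZK669.3 at 1.03, the antimicrobial peptide gene cnc-1 at 1.01, Y75B12B.3 at 0.98, the C-type lectin gene clec-61 at 0.97, txt-4 at 0.97, C18H7.1 at 0.97, and the acid phosphatase gene pho-11 at 0.95 ± 0.09. Of these, pho-11 had the smallest limma adjusted p, 0.00302, and C18H7.1 the largest, 0.0484. The probe sets of cnc-1 and clec-61 carry the suffixes of possible cross-hybridization. After each array was corrected for its trend with gene span, the limma adjusted p rose to 0.0664 for spig-20, whose change went from 1.05 to 0.92, and to 0.0618 for C18H7.1, whose change went from 0.97 to 0.98. After a second quantile normalization it was 0.0543 and 0.0548.

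**Figure D1:**
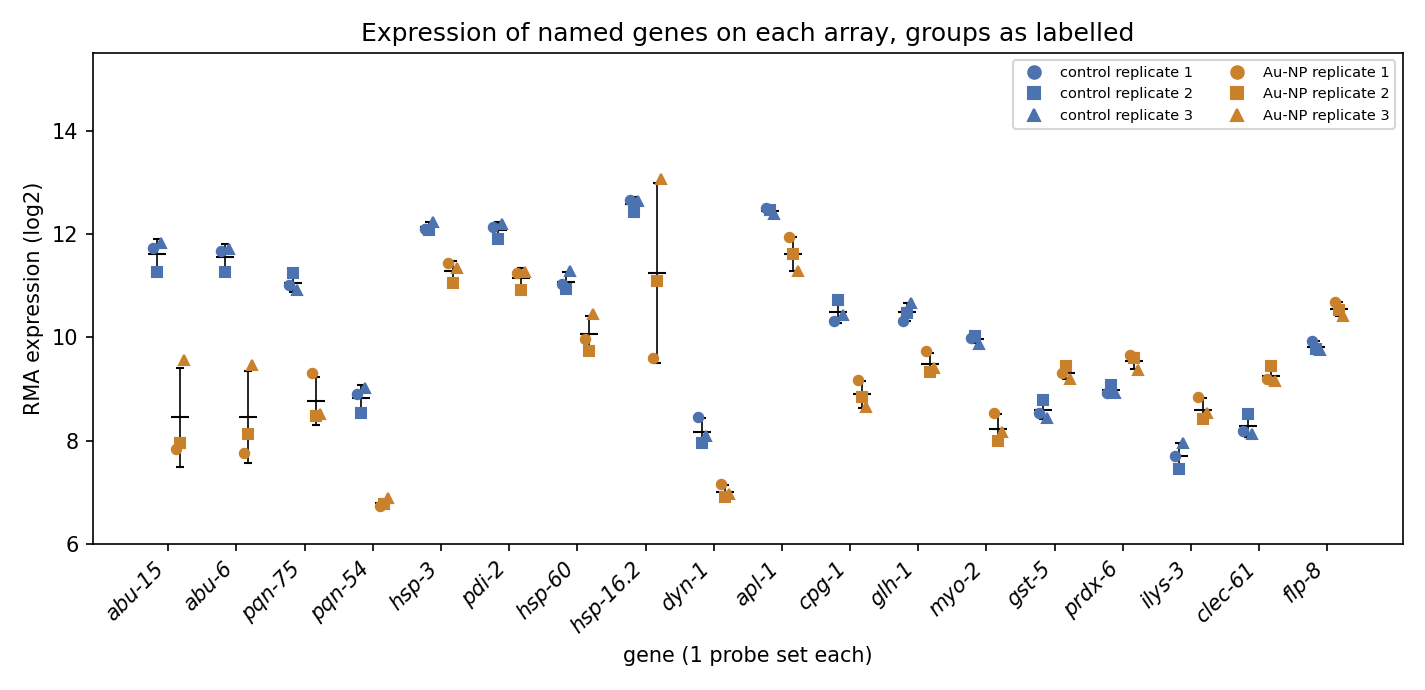
RMA expression (log2) of 18 genes on each of the 6 arrays, 1 probe set per gene, with control arrays in blue, arrays labelled Au-NP in orange, marker shape for replicate number, and horizontal ticks with bars for the group mean and SD (n = 3). The abu-15 values lie at 11.6 on average in the controls and 8.46 in the Au-NP arrays, while Au-NP replicate 3 of hsp-16.2 lies above the controls and the other 2 Au-NP arrays lie below them.

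Calls differed with the length of the gene on the chromosome, introns included, taken from the reference gene table. The median span was 1739 bp for probe sets that were higher, 5861.5 bp for those that were lower and 2373 bp for those not past the threshold. With the probe sets in 5 equal bins of span, 11.7% were higher and 1.16% lower in the shortest bin (up to 1285 bp), and 2.27% were higher and 15% lower in the longest (from 5441 bp). Once each array's trend with span was removed, an alternative chosen after seeing the data, 738 probe sets were higher and 1100 lower. The share of higher calls was then 40.2%, over the 20701 probe sets with a known span, against 52.4% over all 22548. Of the called probe sets with a known span, 1009 of 1180 lower ones and 674 of 1344 higher ones kept their call. The median change of these lower ones went from -0.65 to -0.64 and that of the higher ones from 0.46 to 0.39. Spearman's rho with span of each array's difference from the mean of the controls, other controls for a control array, was -0.27, -0.33 and -0.14 for Au-NP replicates 1 to 3 and 0.14, -0.16 and 0.0016 for control replicates 1 to 3. It was taken across probe sets, which are not independent replicates.

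**Figure D2:**
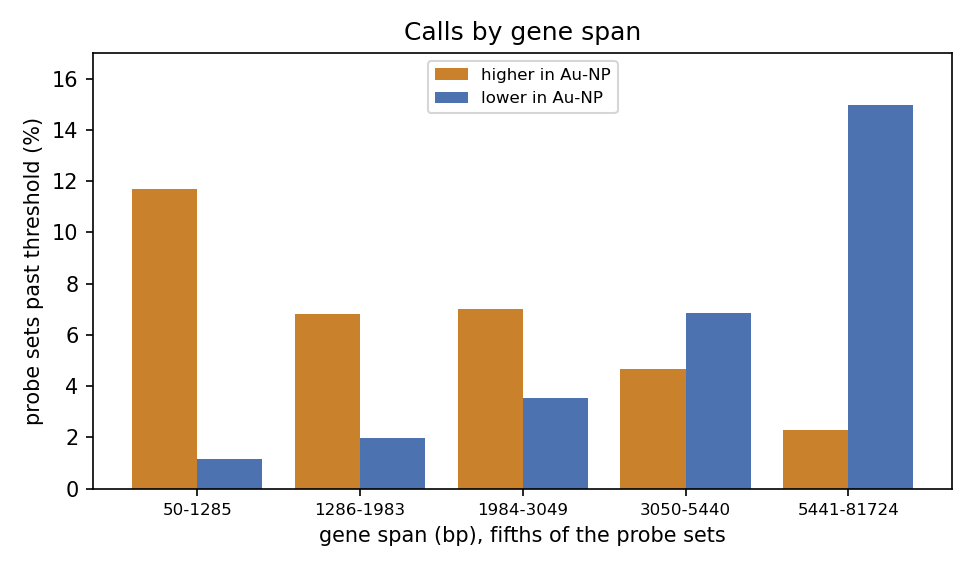
Share of tested probe sets past the threshold (percent, bars from 0) in 5 equal bins of gene span (bp), with higher in Au-NP in orange and lower in Au-NP in blue. The higher share is 11.7% in the bin of shortest spans and 2.27% in that of the longest, where the lower share is 1.16% and 15%.

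Gene lists fixed before the data were examined were tested with camera, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 32 lists. Of these, 13 were lower and 0 higher (15 and 2 at an unadjusted camera p under 0.05). Other splits of the 6 arrays into 3 and 3 gave from 5 to 18 lists past the threshold by the same test. The count of lists thus does not set the labelled groups apart from other groupings. When camera estimated the correlation within each list 0 passed, with a smallest adjusted p of 0.491 and 3 lists at an unadjusted p under 0.05. By fry, which asks only whether a list's genes move one way on balance, 3 lists were lower (the abu and pqn genes, body-wall muscle and the vitellogenins) and 4 were higher (cytochrome P450, ribosomal proteins, the respiratory chain and neurons). The counts of members below use the limma p adjusted over all probe sets, and the count adjusted over the list alone follows each.

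**Figure D3:**
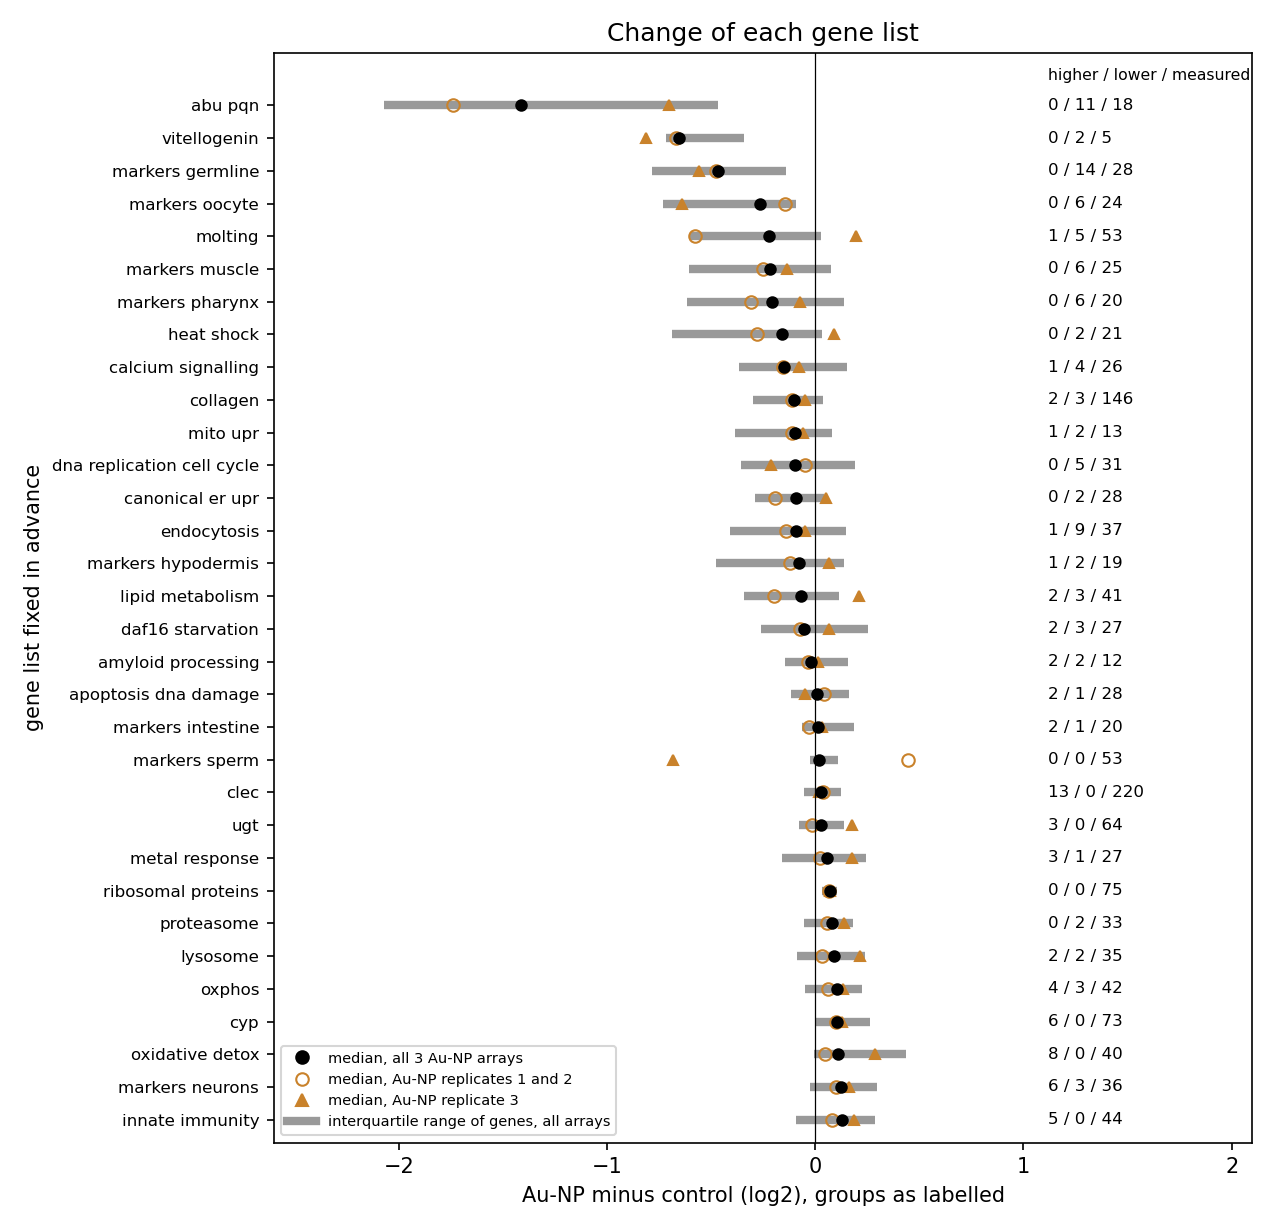
Median log2 difference, Au-NP minus control, of each of the 32 lists for all arrays (black), for Au-NP replicates 1 and 2 (open circles) and for Au-NP replicate 3 (triangles), with grey bars for the interquartile range of the list's genes and the numbers of genes higher, lower and measured at the right. The abu and pqn list has the lowest median, -1.41, and the sperm list differs most between Au-NP replicates 1 and 2 (0.45) and replicate 3 (-0.68).

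In the abu and pqn list, 11 of 18 measured genes were lower, 0 were higher and 7 did not pass, and adjusted over the list alone 14 were lower and 0 higher. Their median was -1.41 log2 (camera adjusted p = 4.75e-14), and the call was lost with an adjusted p = 0.491 with an estimated correlation. All 18 genes had negative values, abu-11 among them at -1.45 ± 0.27 (SE). The uniform sign holds for these list members and not for every pqn gene. Taken by symbol prefix, a grouping made after the results were seen, 16 of 47 pqn genes were lower and 1 higher. Of these 47 genes 11 had positive values, and their median was -0.28, or -0.22 after the correction for gene span. By the same prefix rule 6 of 11 abu genes were lower and 0 higher, with a median of -1.41. The genes pqn-54, pqn-74, pqn-75 and abu-8 had the smallest p of the list. In Au-NP replicate 3 the list's median lay at -0.70 against the control mean, and in Au-NP replicates 1 and 2 at -1.74. The list was drawn from a theme remembered from the study's publication, so its count is not independent evidence.

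Chaperones of 3 compartments had members that were lower. The remembered account of the study also covers several chaperones, so the counts of these lists may not be independent evidence either. Over all 17118 genes, each counted by any of its probe sets, 846 fell and 1282 rose. In the endoplasmic reticulum list 2 of 28 genes fell and 0 rose (adjusted over the list alone, 2 and 0), namely hsp-3, a BiP chaperone, at -0.86 ± 0.11 (SE), and pdi-2, a protein disulfide isomerase, at -0.94 ± 0.13. The median of the list was -0.09 (camera adjusted p = 0.00255, and adjusted p = 0.538 with an estimated correlation). It was -0.19 without Au-NP replicate 3, -0.05 without Au-NP replicate 2 and 0.05 in Au-NP replicate 3 itself. The other BiP gene, hsp-4, had -1.02 ± 0.42 (limma adjusted p = 0.175). In the heat-shock list 2 of 21 genes fell and 0 rose (adjusted over the list alone, 3 and 0), the constitutive Hsp70 gene hsp-1 at -0.69 ± 0.11 and the DnaJ gene dnj-13 at -1.21 ± 0.31. The median of this list was -0.16 (camera adjusted p = 0.00415, and adjusted p = 0.538 with an estimated correlation), and without Au-NP replicate 1 the camera adjusted p was 0.0521. The stress-inducible small heat-shock gene hsp-16.2 had -1.33 ± 0.74 (limma adjusted p = 0.320), with 9.6 and 11.09 in Au-NP replicates 1 and 2, 13.1 in Au-NP replicate 3 and 12.4 to 12.7 in the controls. Without Au-NP replicate 3, hsp-4 had -1.54 and hsp-16.2 had -2.24 (limma adjusted p = 0.00215 and 0.00399). Without Au-NP replicate 1 they had -0.67 and -0.51 (limma adjusted p = 0.391 and 0.657). With array weights hsp-4 had -1.25 (limma adjusted p = 0.0340). The heat-shock list's median was 0.09 in Au-NP replicate 3, -0.28 in the other 2 Au-NP arrays and -0.24 without control replicate 2. Of 13 mitochondrial stress genes, the chaperonin hsp-60 at -1.02 ± 0.19 and the mitochondrial Hsp70 gene hsp-6 at -0.42 ± 0.08 fell and the protease gene clpp-1 at 0.34 ± 0.07 rose. Adjusted over the list alone, 4 fell and 3 rose. The median of that list was -0.10 and it did not pass (camera adjusted p = 0.0932).

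Detoxification genes that passed were nearly all higher, by less than 1 log2 unit, although none of these lists passed camera on the deposited values without rescaling, with all arrays and probe sets and the group alone in the model. In the antioxidant and glutathione list 8 of 40 genes rose and 0 fell (adjusted over the list alone, 12 and 2), with a median of 0.11 (camera adjusted p = 0.0932). The glutathione S-transferase genes gst-5, gst-13 and gst-6 rose by 0.73 ± 0.11, 0.58 ± 0.13 and 0.50 ± 0.09 (SE) and the peroxiredoxin gene prdx-6 by 0.56 ± 0.10. Without control replicate 1 or Au-NP replicate 1 this list passed as higher (camera adjusted p = 0.0457 and 0.00707), as it did without probe sets of possible cross-hybridization (camera adjusted p = 0.0475). The superoxide dismutase gene sod-3 had 0.51 ± 0.14 (limma adjusted p = 0.0575). It passed without control replicate 2 or Au-NP replicate 3 (limma adjusted p = 0.0435 and 0.0312), with array weights (0.0433) and above the median level (0.0428). The gene gst-4 had -0.01 ± 0.17 (limma adjusted p = 0.987). Among 73 cytochrome P450 genes 6 rose and 0 fell (adjusted over the list alone, 4 and 0), with cyp-34A8 at 0.57 and cyp-32A1 at 0.55, a median of 0.10 and a camera adjusted p of 0.0535. The P450 list passed as higher without Au-NP replicate 2 (camera adjusted p = 0.0192), after a second quantile normalization (0.0277) and after median centring (0.0475). The gene cyp-35A2 had 0.30 ± 0.08 (limma adjusted p = 0.0555), and it passed with array weights (0.0266) and above the median level (0.0420). Of 64 UDP-glucuronosyltransferase genes 3 rose and 0 fell (adjusted over the list alone, 1 and 0), among them ugt-60 at 0.52 and ugt-61 at 0.42, with a list median of 0.03 (camera adjusted p = 0.986). That share lay below the one over all genes, of which 1282 of 17118 rose.

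The metal-response list had 3 of 27 genes higher and 1 lower (adjusted over the list alone, 3 and 1). The genes that rose were cdr-2, a cadmium-responsive gene, at 0.50 ± 0.08 (SE), the metallothionein gene mtl-1 at 0.45 ± 0.11 and the ferritin gene ftn-1 at 0.39 ± 0.09. The gene hmt-1, which encodes an ABC transporter for heavy-metal tolerance, fell by 0.76 ± 0.11. The other metallothionein gene, mtl-2, had 0.20 ± 0.12 (limma adjusted p = 0.369) and the phytochelatin synthase gene pcs-1 had 0.14 ± 0.15 (limma adjusted p = 0.645). The metal list had a median of 0.06 (camera adjusted p = 0.989). With the correction for gene span, mtl-1 had 0.32 and ftn-1 0.29 (limma adjusted p = 0.109 and 0.113), and after a second quantile normalization 0.40 and 0.35 (limma adjusted p = 0.0573 and 0.0719). With single arrays left out, mtl-1 kept its call only without Au-NP replicate 3 and ftn-1 only without Au-NP replicate 1. The limma adjusted p otherwise lay between 0.0609 and 0.153 for mtl-1 and between 0.0560 and 0.136 for ftn-1.

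The immunity genes that passed over all probe sets were all higher. In the immunity list 5 of 44 genes rose and 0 fell (adjusted over the list alone, 8 and 1), among them the lysozyme gene ilys-3 at 0.90 ± 0.16 (SE), cnc-1 at 1.01 ± 0.22, clec-86 at 0.62 ± 0.12, and pmk-1, the p38 kinase of the immune pathway, at 0.34 ± 0.08. Its median was 0.13 (camera adjusted p = 0.253). Of 220 C-type lectin genes 13 rose and 0 fell (adjusted over the list alone, 8 and 0), with clec-61 at 0.97 ± 0.13, clec-233 at 0.72 ± 0.09, clec-5 at 0.64 ± 0.10 and clec-72 at 0.55 ± 0.08. Over all 17118 genes, each counted by any of its probe sets, 1282 rose, which is a larger share. The median of the C-type lectin list was 0.03 (camera adjusted p = 0.892), and it was -0.05 after the correction for gene span. Among probe sets above the median level it was 0.30, and the list passed as higher (camera adjusted p = 0.0157). The 2 lists share 5 genes.

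Genes of clathrin-dependent uptake were among those that fell. In the endocytosis list 9 of 37 genes fell and 1 rose (adjusted over the list alone, 9 and 2), with the dynamin gene dyn-1 at -1.15 ± 0.14 (SE), the clathrin adaptor gene unc-11 at -1.1 ± 0.16, the clathrin heavy chain gene chc-1 at -0.72 ± 0.11 and arf-6 at -0.58 ± 0.08. The list's median was -0.09 (camera adjusted p = 0.00152, and adjusted p = 0.511 with an estimated correlation), and it was -0.14 without Au-NP replicate 3. For unc-11 1 of 10 probe sets passed the threshold. The yolk receptor gene rme-2 had -0.49 ± 0.17 (limma adjusted p = 0.117). In the amyloid-processing list apl-1, which encodes the worm's amyloid precursor-like protein, fell by 0.84 ± 0.16 and feh-1, which encodes an adaptor that binds it, fell by 0.82 ± 0.07, whereas the gamma-secretase subunit genes pen-2 and aph-1 rose by 0.55 ± 0.10 and 0.34 ± 0.08. That made 2 of 12 genes higher and 2 lower (adjusted over the list alone, 2 and 2), with a median of -0.02 (camera adjusted p = 0.356). For apl-1 3 of 3 probe sets passed. Of 26 calcium-signalling genes 4 fell and 1 rose (adjusted over the list alone, 7 and 2), with egl-30, a Gq alpha subunit, at -0.89, the calcium pump gene sca-1 at -0.80, the calmodulin gene cmd-1 at -0.42 and the calcineurin subunit gene cnb-1 at 0.42. The median of the calcium list was -0.15 (camera adjusted p = 0.00730, and adjusted p = 0.511 with an estimated correlation), and after the correction for gene span it was 0.01 with a camera adjusted p of 0.637. These 3 lists were drawn from themes remembered from the study's publication, and their counts are not independent evidence. In the lysosome list, cpr-5 and cpl-1, which encode cathepsin proteases, fell by 0.81 ± 0.12 and 0.48 ± 0.10, while lmp-2 and the nuclease gene nuc-1 rose by 0.53 ± 0.11 and 0.56 ± 0.14, so that 2 of 35 genes were higher and 2 lower (adjusted over the list alone, 2 and 2, with a median of 0.09 and a camera adjusted p of 0.848).

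The moulting and collagen lists were lower by camera at the preset correlation but not by fry (fry adjusted p = 0.476 and 0.372). Their medians differed between the Au-NP arrays. In the moulting list 5 of 53 genes fell and 1 rose (adjusted over the list alone, 5 and 1), with lin-42, the worm's period homologue, at -1.22 ± 0.12 (SE), mlt-10 at -0.81 ± 0.13, rab-11.1 at -0.58 ± 0.11 and the hedgehog-related gene grd-3 at 0.53 ± 0.09. The moulting median was -0.22 (camera adjusted p = 2.01e-04, and adjusted p = 0.614 with an estimated correlation), but it was -0.58 in Au-NP replicates 1 and 2 and 0.19 in Au-NP replicate 3. It was -0.04 without Au-NP replicate 1, -0.10 without Au-NP replicate 2 and -0.35 without control replicate 2. Of 146 cuticle collagens 3 fell and 2 rose (adjusted over the list alone, 0 and 0), with dpy-8 at -1.21 ± 0.29, dpy-3 at -0.90 ± 0.20, col-153 at 0.68 ± 0.14 and col-176 at 0.51 ± 0.11. Over all 17118 genes, each counted by any of its probe sets, 846 fell and 1282 rose, which are larger shares than among the collagens. The collagen median was -0.10 (camera adjusted p = 7.98e-05, and adjusted p = 0.528 with an estimated correlation), and it was -0.07 without control replicate 3. The adult collagen gene col-19 had 0.41 ± 0.32 (limma adjusted p = 0.499), with 0.75 and a limma adjusted p of 0.0456 without Au-NP replicate 3. It had 0.15 without Au-NP replicate 2 and 0.17 without control replicate 1. Of 19 hypodermis markers vab-10 at -0.86 and nhr-23 at -0.58 fell and grd-3 rose (adjusted over the list alone, 2 fell and 2 rose). Their median was -0.08 (camera adjusted p = 0.102), and without Au-NP replicate 3 or control replicate 2 the list passed as lower (camera adjusted p = 0.0108 and 0.0345).

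The germ-line and oocyte lists had members that fell, and their medians lay below 0 in Au-NP replicate 3 as well as in replicates 1 and 2. In the germ-line list 14 of 28 genes fell and 0 rose (adjusted over the list alone, 17 and 0), among them nos-3 at -1.21 ± 0.14 (SE), the P-granule genes pgl-3 at -1.0 ± 0.15 and glh-1 at -0.99 ± 0.13, and the RNA helicase gene cgh-1 at -0.78 ± 0.11. The germ-line median was -0.47 (camera adjusted p = 5.57e-11, and adjusted p = 0.511 with an estimated correlation), and it was -0.56 in Au-NP replicate 3. Of 24 oocyte genes 6 fell and 0 rose (adjusted over the list alone, 7 and 0), with the eggshell genes cpg-1 at -1.60 ± 0.16 and cbd-1 at -1.47 ± 0.24, puf-7 at -1.26 ± 0.24 and lin-41 at -1.08 ± 0.07. The oocyte median was -0.27 (camera adjusted p = 2.62e-07, and adjusted p = 0.538 with an estimated correlation), with -0.15 in Au-NP replicates 1 and 2 and -0.64 in Au-NP replicate 3. Of the 5 yolk protein genes vit-4 and vit-5 fell by 0.72 ± 0.08 and 0.65 ± 0.13 (adjusted over the list alone, 3 fell and 0 rose), with a list median of -0.65 (camera adjusted p = 3.02e-04, and adjusted p = 0.491 with an estimated correlation). The gene vit-2 had -1.56 ± 0.46 (limma adjusted p = 0.0688), and it passed without Au-NP replicate 3, with -0.97 (limma adjusted p = 0.00399), and with array weights (limma adjusted p = 0.0430). Among 53 spermatogenesis genes 0 passed in limma, over all probe sets or adjusted over the list alone (1 lower and 0 higher at an unadjusted p under 0.05). That 1 was spd-5, which encodes a centrosome protein, at -0.31, while spe-12 had 0.12 and fer-1 had -0.20, and 34 of the 53 values were positive. The sperm median was 0.02 over all arrays (camera adjusted p = 0.356), 0.45 in Au-NP replicates 1 and 2, where the list passed as higher without replicate 3 (camera adjusted p = 7.65e-06), and -0.68 in Au-NP replicate 3. Without Au-NP replicate 2 its median was -0.19 and it passed as lower (camera adjusted p = 0.00164).

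The muscle and pharynx lists had members that fell, myosin heavy chain genes among them, though most members did not pass. Of 25 body-wall muscle genes 6 fell and 0 rose (adjusted over the list alone, 7 and 1), with unc-52, the perlecan of the muscle attachment matrix, at -1.37 ± 0.13 (SE), the myosin heavy chain genes unc-54 at -0.97 ± 0.13 and myo-3 at -0.75 ± 0.14, and unc-89 at -0.76 ± 0.07. The list's median was -0.22 (camera adjusted p = 2.01e-04, and adjusted p = 0.491 with an estimated correlation). Of 20 pharynx genes 6 fell and 0 rose (adjusted over the list alone, 7 and 5), with the pharyngeal myosin genes myo-2 at -1.73 ± 0.14, myo-1 at -1.32 ± 0.15 and myo-5 at -0.61 ± 0.12, and the organ's transcription factor gene pha-4 at -0.64 ± 0.12. The pharynx median was -0.21 (camera adjusted p = 0.00319, and adjusted p = 0.511 with an estimated correlation). Without probe sets of possible cross-hybridization the camera adjusted p was 0.130. Of 36 neuron markers 6 rose and 3 fell (adjusted over the list alone, 6 and 3), with the neuropeptide genes flp-8 at 0.72 ± 0.10, flp-21 at 0.65 ± 0.09 and nlp-21 at 0.52 ± 0.08, and ida-1, which encodes a protein of the dense-core vesicle, at -0.83 ± 0.12. The neuron median was 0.12 (camera adjusted p = 0.204, and 0.00307 as higher after the correction for gene span). Of 20 intestine markers elt-7 at 0.49 and ftn-1 rose and the actin gene act-5 at -0.85 fell (adjusted over the list alone, 2 rose and 1 fell, with a median of 0.01 and a camera adjusted p of 0.848).

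The cell-cycle, respiratory-chain, ribosome, proteasome and cell death lists had medians between -0.09 and 0.10. Of 31 replication and cell-cycle genes 5 fell and 0 rose (adjusted over the list alone, 8 and 3), with the replicative helicase genes mcm-4 at -1.13 ± 0.13 (SE), mcm-2 at -1.07 ± 0.11 and mcm-7 at -0.69 ± 0.14, and the ribonucleotide reductase gene rnr-1 at -0.81 ± 0.15. The list's median was -0.09 (camera adjusted p = 0.0149, and adjusted p = 0.614 with an estimated correlation). It was -0.16 without control replicate 1. It did not pass without control replicate 3 or Au-NP replicate 3 (medians -0.04 and -0.05, camera adjusted p = 0.0643 and 0.0770) or without probe sets of possible cross-hybridization (median -0.02, camera adjusted p = 0.1997). Of 42 respiratory-chain genes 4 rose and 3 fell (adjusted over the list alone, 6 and 4), with the succinate dehydrogenase gene sdha-1 at -1.15 ± 0.09, nuo-5 at -0.92 ± 0.14, the ATP synthase gene atp-1 at -0.44 ± 0.08 and cox-17 at 0.52 ± 0.08 (median 0.10, camera adjusted p = 0.370). Of 75 ribosomal protein genes 0 passed in limma (adjusted over the list alone, 0 likewise, with 1 higher and 1 lower at an unadjusted p under 0.05), with rpl-14 at 0.22 and rpl-7A at -0.19, and their median was 0.07 (camera adjusted p = 0.204). It became -0.05 after the correction for gene span, where the list passed as lower (camera adjusted p = 0.00811). Among 33 proteasome genes rpn-1 at -0.76 and pbs-2 at -0.34 fell and 0 rose (adjusted over the list alone, 1 fell and 0 rose, with a median of 0.08 and a camera adjusted p of 0.986). In the cell death and DNA damage list of 28 genes ced-4 at 0.40 and nuc-1 rose and wah-1 at -0.45 fell (adjusted over the list alone, 2 rose and 1 fell, with a median of 0.01 and a camera adjusted p of 0.509).

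The starvation and lipid lists did not pass, and each had members that fell and members that rose. In the starvation and DAF-16 list 3 of 27 genes fell and 2 rose (adjusted over the list alone, 4 and 3), with the TFEB homologue hlh-30 at -1.79 ± 0.20 (SE), the glyoxylate cycle gene icl-1 at -0.94 ± 0.23, the gluconeogenic gene pck-1 at -0.81 ± 0.15 and the lipase gene lipl-3 at 0.49 ± 0.08 (median -0.06, camera adjusted p = 0.271). In the lipid metabolism list 3 of 41 genes fell and 2 rose (adjusted over the list alone, 3 and 2), with the acetyl-CoA carboxylase gene pod-2 at -1.32 ± 0.11, the SREBP gene sbp-1 at -0.49 ± 0.09, the lipid-binding protein gene lbp-1 at 0.46 ± 0.10 and the desaturase gene fat-4 at 0.34 ± 0.07. The lipid median was -0.07 (camera adjusted p = 0.0535). Without Au-NP replicate 3 it was -0.20 and the list passed as lower (camera adjusted p = 2.30e-05). It also passed without control replicate 2 (camera adjusted p = 0.00245), after a second quantile normalization (0.0251), after median centring (0.0405) and with array weights (0.0126). The list median was 0.21 in Au-NP replicate 3 itself. For the cell death, intestine and sperm lists the median, the mean and the direction given by camera differed in sign. Without probe sets of possible cross-hybridization the medians of the mitochondrial stress (0.02), lysosome (-0.04) and amyloid-processing (0.07) lists turned sign. Without genes shared between lists that of the hypodermis list did (0.08), and none of these 4 lists passed there. After the correction for gene span the medians of the metal-response (-0.0054), UDP-glucuronosyltransferase (-0.02), proteasome (-0.01), respiratory-chain (-0.00016) and sperm (-0.07) lists lay below 0 too, and that of the intestine list did (-0.0079) after a second quantile normalization. Of the 129 probe sets named here and under the other observations that passed the threshold, 57 stayed past it whichever single array was left out.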

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

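The correction for gene span was chosen after seeing the data, and all other settings were set in advance. Of 145 named probe sets 129 passed the threshold, and 113 of these kept the call in 8 settings with all arrays, where they were tested. These were the replicate block, quantile normalization again, median centring, both level filters, array weights, the removal of possible cross-hybridization and the span correction. Of the 129, 57 kept it whichever array was left out, where fewer arrays enter the fit. In all of these settings 0 of the 129 changed sign. Leaving out an array could not have changed one, since the groups of called probe sets did not overlap. Only settings that alter the values (quantile normalization again, median centring and the span correction) could have. Trend and robust variances kept 122 of them, a minimum of 1.5-fold kept 90 and gene-wise variances kept 4. The span correction ended 14 named calls, all higher, with changes of 0.26 to 0.98 against 0.34 to 1.05 before. With 1 array left out at a time, the count of higher probe sets ranged from 146 to 2047, of lower ones from 410 to 1953, of higher genes from 137 to 1848, of lower genes from 284 to 1392, of lower lists from 12 to 15 and of higher lists from 0 to 1. Without Au-NP replicate 3, 4000 probe sets passed, 2465 of them shared with the 2689 called on all arrays.

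The deviations from the group means of arrays of the same number correlated at -0.33, 0.43 and 0.22 across probe sets. With 3 arrays per group these deviations are tied to one another, so the values do not decide whether the numbers pair the arrays. With the replicate number as a block 1100 probe sets were higher and 1173 lower, and 14 lists were lower, lipid metabolism added (camera adjusted p = 0.0209), and 1 higher, cytochrome P450 (camera adjusted p = 0.0438). The block ended 9 named calls (spig-20, clpp-1, ftn-1, aph-1, pmk-1, fat-4, lbp-1, pbs-2 and ced-4, limma adjusted p from 0.0504 to 0.0946) and gained hsp-4 (limma adjusted p = 0.0441).

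Array weights gave 2372 higher probe sets and 2124 higher genes. Without probe sets of possible cross-hybridization, which leaves 15837 to test, 628 were lower and 488 genes were lower. With gene-wise variances 33 probe sets were higher and 39 lower (33 and 36 genes). At an adjusted p of 0.1 there were 2484 higher probe sets (2236 genes). At 0.05 with at least 1.5-fold there were 259 higher and 753 lower (230 and 496 genes), at an unadjusted p of 0.01 with 1.5-fold 272 and 786 (243 and 517 genes), and at an unadjusted p of 0.05 alone 3638 and 2342 (3227 and 1556 genes). Taking 1 probe set per gene left 746 lower probe sets. The counts at other thresholds follow from their construction. Without possible cross-hybridization and with 1 probe set per gene, lower calls went down by a larger share than the probe sets tested, while 997 and 1178 higher ones passed, and the cause was not tested there, for array weights or for gene-wise variances.

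The correction for gene span, on the 20701 probe sets with a known span, gave 738 higher probe sets and 695 higher genes. The share of higher calls there was 40.2%, against 52.4% over all 22548 probe sets. It was 61.4% without probe sets of possible cross-hybridization and stayed within 10 points of 52.4% after quantile normalization (47.2%) or median centring (54.9%). With an estimated correlation 0 lists were lower, and by fry 3 were lower and 4 higher. Besides the block, 1 list was higher in 5 other settings with all arrays, and the cause was not tested. It was cytochrome P450 after quantile normalization again (camera adjusted p = 0.0277) and median centring (0.0475), C-type lectins above the median level (0.0157), the antioxidant list without possible cross-hybridization (0.0475) and neurons after the correction for gene span (0.00307). With arrays left out, 1 list was higher without control replicate 1 or Au-NP replicate 1 (antioxidant), without Au-NP replicate 2 (cytochrome P450) and without Au-NP replicate 3 (sperm). The median of 15 lists changed sign in at least 1 setting, and 3 of these passed there or on the deposited values. The calcium list lost its call with 0.01 after the span correction (camera adjusted p = 0.637). The sperm list had a median of 0.45 without Au-NP replicate 3 (camera adjusted p = 7.65e-06) and -0.19 without Au-NP replicate 2 (camera adjusted p = 0.00164), against 0.02 on all arrays, and the ribosomal list a median of -0.054 after the correction for gene span (camera adjusted p = 0.00811), and the cause was not tested. Signal over background could not be judged, because detection calls were not used here.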

Other observations

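The tests here were all chosen after the results were seen. Genes and families named here outside the report were chosen after their values were seen. Sorting genes by the prefix of their symbol gave 165 families of at least 10 measured genes, 26 of which passed camera with Benjamini-Hochberg adjustment and 0 with an estimated correlation (12 at an unadjusted p under 0.05). Families of signalling peptides had members that rose, though most of each did not pass. Of 58 nlp neuropeptide genes 28 were higher and 0 lower, with a median of 0.40, and nlp-20 rose by 0.70 ± 0.08 (SE). Of 25 flp neuropeptide genes 10 were higher and 0 lower (median 0.37), with flp-10 at 0.90 ± 0.12, and of 23 insulin-like ins genes 7 were higher and 0 lower (median 0.31). Of 10 rpb genes for RNA polymerase subunits 7 were higher and 0 lower (median 0.37, rpb-5 at 0.45 ± 0.07), and of the mitochondrial ribosomal protein genes 7 of 34 mrpl and 8 of 25 mrps genes were higher and 0 lower (medians 0.24 and 0.23, mrpl-48 at 0.56 ± 0.08). The camera adjusted p of these 6 families ranged from 9.88e-10 for nlp to 0.00120 for rpb, and their adjusted p with an estimated correlation from 0.389 to 0.652.

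Some genes of the nuclear pore fell. Of 26 npp nucleoporin genes 9 were lower and 0 higher (median -0.22, camera adjusted p = 4.11e-06, and adjusted p = 0.634 with an estimated correlation), with npp-11 at -1.31 ± 0.16 (SE), npp-8 at -1.31 ± 0.12 and npp-10 at -0.96 ± 0.09. Of 13 klp kinesin-like genes 5 were lower and 0 higher (median -0.15, camera adjusted p = 0.00146, and adjusted p = 0.634 with an estimated correlation), with klp-7 at -0.98 ± 0.12. The medians of all 8 families kept their sign after quantile normalization again, median centring, span correction and the removal of Au-NP replicate 3. After the span correction they were -0.22 for npp and -0.10 for klp. They were 0.32 for nlp, 0.30 for flp, 0.21 for ins, 0.25 for rpb, 0.14 for mrpl and 0.12 for mrps. Before it, mrpl and mrps had 0.24 and 0.23.

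Lower calls lay in genes of long span and higher calls in genes of short span. The average trend with span was small beside the lower calls, with median changes of 0.08 in the shortest bin of span and -0.06 in the longest. Of the lower calls 85.5% stayed past the threshold once each array's trend was removed, and their median went from -0.65 to -0.64. Removing so small a trend could undo few falls of this size, so the share that stayed does not decide whether span was the cause. Of the higher calls 50.1% stayed, with medians of 0.46 and 0.39. A span effect that differs between genes of like span was not removed and stays open. Short span as the cause of the higher neuropeptide values stays open, since the median of the 106 nlp, flp and ins genes went from 0.38 to 0.29 with that correction, but no more than 19 of their 45 higher calls stayed past the threshold. RNA breakdown or labelling cut short in the Au-NP arrays stays open, since the gap between 3' and 5' probe sets of 4 control transcripts changed by -0.0086 log2 (two-sided exact permutation test, p = 0.9, where 3 against 3 allows no p below 0.1), but these transcripts are short. Of the 77 Affymetrix control probe sets 2 were lower and 0 higher past the threshold, adjusted over the control probe sets alone. Both were of worm catalase, at -0.45 and -0.47 log2 (limma adjusted p = 0.0275 for each), and the cause was not tested. The trend with span was as strong in control replicate 2 (Spearman's rho across probe sets -0.16) as in Au-NP replicate 3 (-0.14), and a change of long-gene transcription with exposure, with -0.27 and -0.33 in Au-NP replicates 1 and 2, was not tested and stays open.

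Au-NP replicate 3 lay apart from replicates 1 and 2. RNA of control worms mixed into it is argued against, since on a scale from 0 at the control mean to 1 at the mean of replicates 1 and 2 its germ-line genes lay at 1.28 and its moulting genes at 0.02, a difference of 1.26 where mixing would put both at about the same place. Worms of another developmental time may account for the distance, as a hypothesis, because its median departure from replicates 1 and 2 was 0.40 log2 in the lists that follow stage, 2.78 times that of random lists matched on level (0.15), with the sperm, moulting and oocyte lists departing most (1.20, 0.77 and 0.53). The random lists were not matched on how genes vary together, and the estimated correlation was 0.79 for sperm and 0.52 for moulting. No other array was compared in this way, so the ratio does not single out developmental time. The germ-line list departed by 0.23 against 0.16 in its random lists, 95% of which lay between 0.10 and 0.25, which decides nothing for that list. Whether exposure itself shifted the timing of 1 dish was not tested.

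Of the 12 largest falls 6 were of abu and pqn genes, and falls were not confined to probe sets marked for cross-hybridization. Of the 13 unmarked probe sets 46.2% (6, with a median of -1.39 log2 over all 13) were lower past the threshold. That share was reached by 1 of 10000 random sets matched on level. Those sets were drawn 1 probe set at a time, while the list's genes vary together (estimated correlation 0.48), so this count can overstate the evidence. The comparison was also taken up after 2 bounds were not met by the same values. One asked that most unmarked probe sets pass and one was on their upper quartile, which lay at -0.09. Without marked probe sets the list kept its call (median -1.29 over 10 genes, camera adjusted p = 2.94e-07, and adjusted p = 0.569 with an estimated correlation). Signal shared between unmarked probe sets was not tested, and whether shared signal was the whole cause stays open. The place of each dish in the moulting cycle cannot be told apart from exposure, since these genes lay at -0.70 in Au-NP replicate 3, where the moulting list lay at 0.19, but that is a single array and moulting genes peak at different times. A direction opposite to the remembered account could come from exchanged group labels or from a mistaken recollection, and neither can be excluded, because the recollection was not checked, and because hsp-16.2, hsp-4 and hsp-70 were at or above the percentile of 95.6 among all probe sets in each array labelled control, yet also lay at 96.8 or above in Au-NP replicate 3. Of these, hsp-70 had -1.89 ± 0.88 (SE, limma adjusted p = 0.229, with -3.01 and 0.00118 without Au-NP replicate 3). The metal and detoxification genes mtl-1, cdr-2 and gst-5 were higher in the arrays labelled Au-NP by 0.45, 0.50 and 0.73 log2. They are picked members. In the metal list 3 of 27 genes rose and 1, hmt-1, fell (median 0.06, camera adjusted p = 0.989). In the antioxidant list 8 of 40 rose and 0 fell (median 0.11, camera adjusted p = 0.0932). These genes thus do not settle the direction.

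The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2689 probe sets past the threshold and the highest of the others 0 (5980 and at most 2719 by limma at an unadjusted p under 0.05), so that 1 split reached the real count. For the gene lists by camera with the preset correlation, the real split gave 13 and the highest of the others 18, in which control replicates 1 and 3 and Au-NP replicate 3 stood against the rest, and 4 splits reached the real count. Every other split gave at least 5 lists, so the count of 13 does not set the labelled groups apart from other groupings of the arrays. The split with 18 lists separates arrays across the groups, and whether it reflects a structure of the samples beyond the labels was not tested.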
